A study of Mus musculus with 75 samples.

How the data were processed

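The starting points were 3 RNA-seq tables of raw counts per gene and 32 4C-seq tables of reads per restriction fragment. Per the submitters' processing notes the gene counts were made from reads aligned to mm10, with HISAT2 2.1.0, HTSeq 0.9.1, DESeq2 1.18.1, Bowtie2 2.3.1 and MACS2 2.2.7.1 named without role or order. The deposited 4C tables give a count of reads per fragment, and the program that made them is not stated. The Hoxb tables add a q-value per fragment computed by the authors before deposit by an unstated method. That q-value was read only to count fragments under 0.05 per library (336 to 851, of which 11 to 99 lay on the chromosome of the bait) and was not used in any test. The 20 H3K27Ac and input samples were not analysed here. Deletion coordinates and strand are not given in the labels.

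The knockout and overexpression tables held 52535 entries each, and that of the enhancer deletions held 52636. Of the latter, 52403 gene identifiers were matched to symbols and 233 kept their identifier. Gene names turned into dates by a spreadsheet numbered 26 in each of the former tables, and repeated names numbered 2 in each and 74 in the enhancer table, and all were kept as separate genes. Columns were matched to samples by title. In the enhancer table the mutant columns are coded Ac and b, and these were matched to Cyp26-E1 and Cyp26-E2 because the 4C tables of those baits are coded a and b. The codes Ac and a are not the same, so this match stays unsure. Titles of the Cyp26-E2 RNA samples name the enhancer without the word knockout, and they were read as its deletion. All columns of per-sample values were used.

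Counts of all groups of a table were fitted together in edgeR 4.0.16, with TMM scaling, filterByExpr at a minimum count of 10, and the robust quasi-likelihood test. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. CPM are counts over the TMM-scaled library size, and log2 CPM used a prior count of 2. The tests covered 16445, 16914 and 18768 genes in the knockout, overexpression and enhancer tables. Standard errors are the absolute log2 fold change over the square root of the F statistic. Comparisons were each mutant against its control, mutant against mutant, and in the knockout table the departure of RARX-DKO from the sum of the other two effects. For genes with 0 counts in a group a bound was given from a floor of 3 counts over the TMM-scaled library sizes of the group in place of the fitted log2 fold change. Intervals, bounds and floors cover counting error only.

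Gene lists numbered 21: RA signalling and metabolism, Hoxa, Hoxb, Hoxc with Hoxd, Hox cofactors with Cdx genes, naive pluripotency, formative and primed pluripotency, extraembryonic endoderm, neuroectoderm, mesoderm and primitive streak, trophectoderm, 2-cell-like state, germline and meiosis, fibroblasts, p53 targets, imprinted genes, neighbours of Cyp26a1 on chromosome 19, neighbours of Hoxb on chromosome 11, ribosomal proteins, glycolysis and hypoxia, and cholesterol synthesis. Lists with 5 or more tested members went through camera of limma 3.58.1 with a preset correlation of 0.01, and with an estimated correlation as the alternative. Counts of members are given over all tested genes and adjusted over the list alone. The comparisons, lists, thresholds and alternatives were fixed before the data were examined. By the rule fixed then, Rara and Rxra, or Cyp26a1 and Cyp26c1, were always named. So were up to 5 of the largest rises and 5 of the largest falls that passed, had a mean log2 CPM of 1 or more and did not overlap between groups, and up to 3 passing members per list with the largest change, or 2 for mutant against mutant. Hoxb1, Rarb and Cyp26a1 could be named everywhere, and gene models without a name were passed over. Genes outside this rule are said in the text to be chosen after their values were seen.

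Each 4C bait was placed at the 10-kb window with the highest sum of reads. That window and 2 on each side were left out, and windows within 1 Mb with a mean of 10 or more reads were tested by edgeR's quasi-likelihood test with the sum over windows as library size. Gene contacts were tested the same way in 5 kb on each side of gene starts. Gene positions are those of GENCODE vM21 on mm10. Genes around the Cyp26-E2 bait and Skap1 were added once the bait position was known. Within pairs of Cyp26 libraries nearly all fragments were shared, so the tests at those baits compare libraries. The Rxra-KO pair at Cyp26-E2 differed no more than counting error (a ratio of 0.98 to counting variance), and its reads were averaged to 1 sample. Tests of it take their spread from the other pairs. Their calls are reported only as counts, within a total over all baits and under alternative settings. No conclusion is drawn from these counts. Strand of origin was not available, so reads of Hotairm1 and of other antisense genes may include sense transcripts, and reads of near-identical copies such as the Zscan4 genes cannot be assigned with certainty.

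The RNA tests were checked on simulated data built from the measured spread. A 2-fold change was found in 53.1%, 80.6% and 68.4% of changed genes, and a 4-fold change in 80.4%, 92.9% and 87.9%, in Rara-KO, Rara-OE and Cyp26-E1-KO. False calls were 8 of 138, 15 of 186 and 15 of 169. A shifted naive pluripotency list was found in all 3 tables with 0 other lists called. Genes were drawn independently of each other there, so false calls of lists whose genes are correlated were not tested. In the 4C tests 0 of 20 windows changed 4-fold were found at either Hoxb bait, 3 and 5 at 16-fold and 8 and 7 at 64-fold, and 20 of 20 at the Cyp26 baits, where the spread is that between libraries with the same fragments. Overlaps between comparisons with a common control were set beside 20 simulated runs with unchanged groups. Libraries were also checked for duplicates. The variance between replicates over counting variance was 7.54 to 13.83 in the knockout table, where Rara-KO replicate 2 and RARX-DKO replicate 1 came as close as 4.9.

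Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, scaling by library totals only, no filter, a CPM of 1 or more, a change of 2-fold or more, replicate numbers as a block, fitting the compared groups alone, leaving out each library, and for 4C 20-kb and 5-kb windows, a range of 500 kb, leaving out the bait window only, TMM, whole-library totals, thinning to equal reads and 2.5 kb around gene starts. Added later were leaving out genes on chromosomes 6, 8, 16 and Y, or on chromosomes 2, 6, 8, 10, 16 and Y, counting covered fragments in place of reads, and keeping the Rxra-KO pair at Cyp26-E2 as 2 libraries. Scripts ran in R 4.3.3 with data.table (version 1.17.8) and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.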

Results

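RNA-seq and 4C-seq, which maps the contacts of a chosen genomic viewpoint or bait, were collected from mouse E14 embryonic stem cells differentiated for 24 h with 2 µM retinoic acid (RA) after withdrawal of LIF and 2i. The 75 samples of the series were 23 RNA-seq libraries, 32 4C-seq libraries and 20 H3K27Ac ChIP-seq and input samples, and the last were not analysed here. RA signals through heterodimers of retinoic acid receptors (RARs) and retinoid X receptors (RXRs). The receptor knockout table held WT, Rara-KO, Rxra-KO and combined RARX-DKO cells (n = 2 each, 7408691 to 13052102 counts per library). The overexpression table held the vector control V-OE, Rara-OE and Rxra-OE (n = 2 each, 7835519 to 11453063 counts). The enhancer table held WT and cells with the Cyp26-E1 or Cyp26-E2 enhancer deleted (n = 3 each, 28397794 to 33601996 counts), with column codes matched to the deletions through similar codes of the 4C tables, a match that stays unsure. The 4C-seq libraries used 2 Hoxb baits (Hoxb-E1, Hoxb-E2) and 2 Cyp26 baits (Cyp26-E1, Cyp26-E2), each in WT, Rara-KO, Rxra-KO and RARX-DKO cells (n = 2 libraries per bait and genotype). All RNA-seq and 4C-seq samples carry 24 h of RA in their labels, so RNA levels and contacts before RA were not measured. The labels call the replicates biological without saying whether they were separate cultures, and every p-value here measures only the spread between these samples. In the overexpression table the variance within groups was 1.9 to 2.28 times the counting variance. That was less than in the knockout table of similar depth, at 7.54 to 13.83 times. In the enhancer table it was 5.49 to 50.18 times, or 5.49 to 9.58 times without Cyp26-E1-KO replicate 2. This ratio grows with the counts per library, which were higher in the enhancer table, so it does not rank that table against the others. Expression is given as CPM (mean ± SD), and changes as log2 fold changes (log2FC ± SE) with edgeR's adjusted p.

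**Figure D1:**
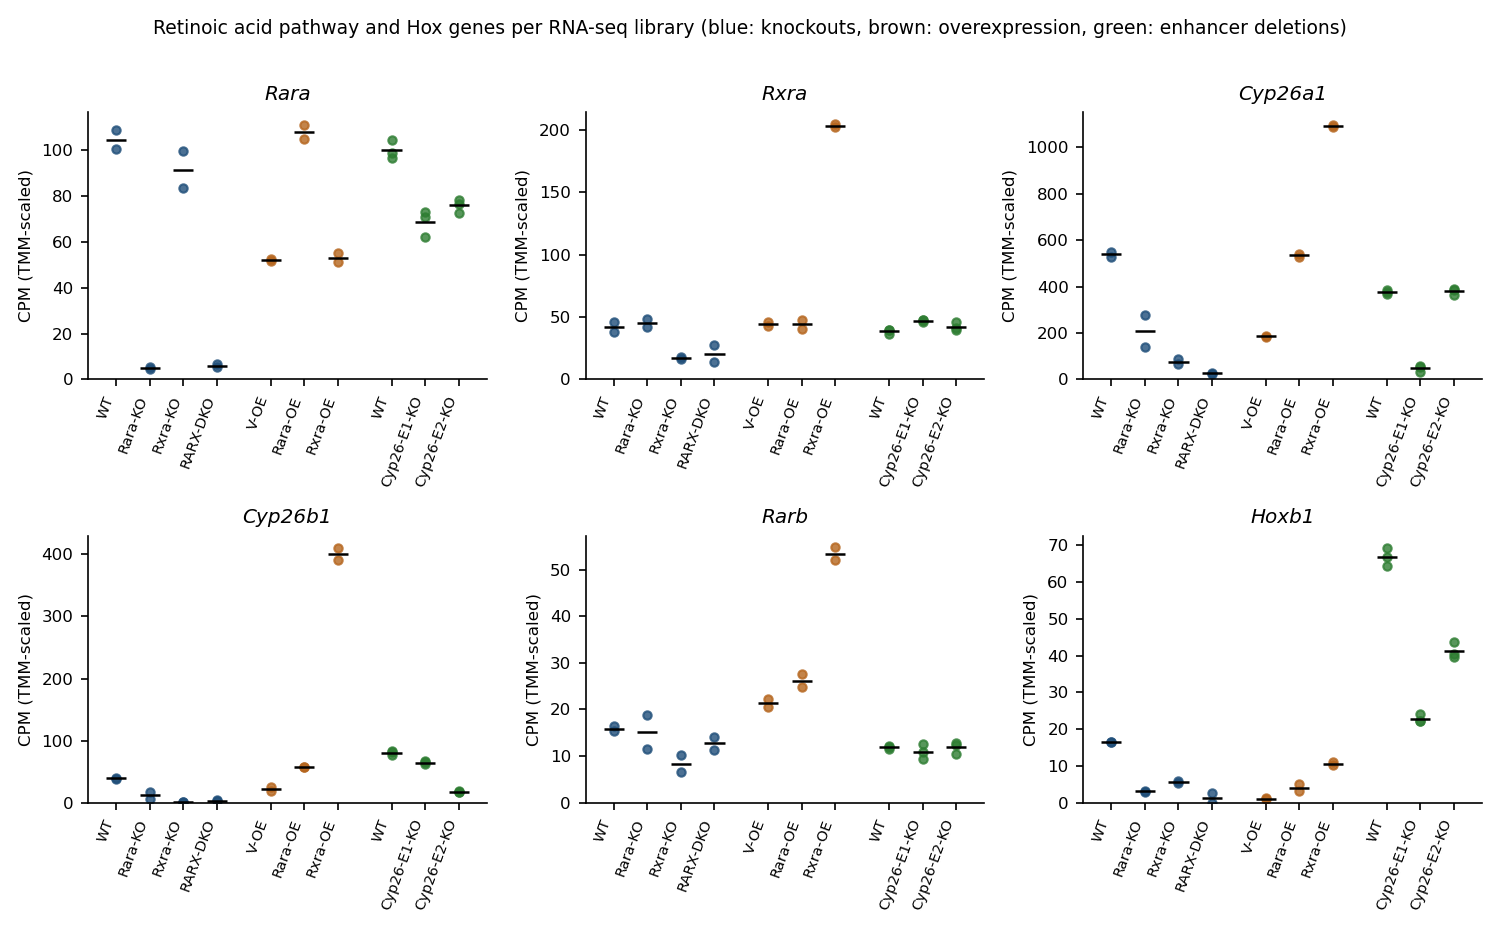
CPM of Rara, Rxra, Cyp26a1, Cyp26b1, Rarb and Hoxb1 (y axes) in each RNA-seq library of the 10 groups (x axes), with points for libraries and bars for group means. Cyp26a1 averaged 538 CPM in the WT of the knockout table and 26.5 CPM in RARX-DKO, and 1092 CPM in Rxra-OE against 185 CPM in V-OE.

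The comparison of Rara-KO with WT asked which genes of the RA response depend on this receptor. Rara (chromosome 11, 98927818 to 98974942, mm10) fell to 5.35 and 4.37 CPM in the Rara-KO libraries, from a WT mean of 104 ± 6.03 CPM (log2FC -4.42 ± 0.19, adjusted p = 7.25e-08). Rxra stood at 45.4 ± 4.54 CPM against 42.1 ± 5.49 CPM (adjusted p = 0.92). Nanog, a core pluripotency factor, rose from 440.1 ± 40.5 to 920.2 ± 111 CPM (log2FC 1.06 ± 0.18, adjusted p = 0.022). Gata6, which specifies primitive endoderm, fell from 50.9 ± 0.28 to 21.3 ± 3.81 CPM (log2FC -1.25 ± 0.17, adjusted p = 0.00963). Of 20 naive pluripotency genes, 3 rose over all genes tested (Nanog, Prdm14 and the lysosomal enzyme Manba) and 9 when adjusted over the list alone. The list had a median log2FC of 0.52 (adjusted p = 1.49e-07 by camera, adjusted p = 0.3 with an estimated correlation). Of 20 extraembryonic endoderm genes, Gata6 fell over all genes and 12 fell when adjusted over the list alone, with a list median of -0.66 (adjusted p = 1.49e-07, and adjusted p = 0.3 with an estimated correlation). Genes that degrade RA did not pass the test here. Cyp26a1, the main RA-degrading cytochrome P450, stood at 141 and 279.5 CPM in Rara-KO against 538 ± 17.2 CPM (log2FC -1.36 ± 0.28, adjusted p = 0.0711), and Cyp26c1 had a log2FC of -1.06 (adjusted p = 0.247). Cyp26b1, a gene chosen after its values were seen, stood at 12.1 ± 8.27 CPM against 39.4 ± 1.10 CPM (log2FC -1.71, adjusted p = 0.0711).

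Other gene groups moved in both directions. The Hoxa list was not called (12 genes, adjusted p = 0.818, median -0.13 but mean 0.51), yet its posterior members Hoxa9 (log2FC 2.14 ± 0.42, adjusted p = 0.0382) and Hoxa10 (1.98 ± 0.33, adjusted p = 0.022) rose. Over the list alone 4 genes were higher and 2 lower. The anterior RA target Hoxb1 (log2FC -2.42 ± 0.67, adjusted p = 0.188) and the receptor gene Rarb (-0.08, adjusted p = 0.954) did not pass. The Hoxb list of 12 genes had a median of -1.07 with no member called alone (adjusted p = 0.00561, and adjusted p = 0.674 with an estimated correlation). The RA signalling list (19 genes) had a median of -0.29, with Rara called over all genes and 4 falls over the list alone (adjusted p = 0.00505, and adjusted p = 0.3 with an estimated correlation). The germline list of 15 genes had a median of 0.51, with the meiotic cohesin gene Smc1b (log2FC 1.67 ± 0.28) called over all genes and 2 rises over the list alone (adjusted p = 0.00505, and adjusted p = 0.307 with an estimated correlation). The imprinted growth regulator Grb10 fell from 291 ± 3.74 to 58.8 ± 7.86 CPM (log2FC -2.31 ± 0.23, adjusted p = 0.000951). The largest rises were those of the citrate transporter Slc13a5 (log2FC 3.16), Nrk (2.93), Trp53tg5 (2.24), Hoxa9 and the P-cadherin gene Cdh3 (2.02). The 5 largest falls were Y-linked. Eif2s3y, Ddx3y, Uba1y, Uty and Zfy1 had 0 counts in both Rara-KO libraries and were at least 329-, 270-, 182-, 92.7- and 34.4-fold lower than in WT (floor of 3 counts over the group, and floors cover counting error only). In all, 106 of 16445 genes changed, 64 up and 42 down. Of these, 4 rose and 17 fell on chromosome 2, 28 rose and 1 fell on chromosome 10, and the count was 28 with chromosomes 2, 6, 8, 10, 16 and Y left out. The count was 9 or 8 without WT replicate 1 or 2, and 10 or 29 without Rara-KO replicate 1 or 2. Of the genes named here Rara, Grb10, Eif2s3y, Ddx3y, Uba1y and Uty kept their calls with each library left out. The count was 259 by DESeq2, 551 without the filter on low counts, 588 with WT and Rara-KO alone in the fit and 55 at 2-fold or more.

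Deleting Rxra lowered the RA-degrading enzymes, Hoxa genes and Cdx1. Rxra (chromosome 2, 27676440 to 27762957) fell to 18.4 and 16.1 CPM from a WT mean of 42.1 ± 5.49 CPM (log2FC -1.29 ± 0.27, adjusted p = 0.0264), so transcripts were still counted. The call was lost without any 1 of the 4 libraries. Rara stood at 91.3 ± 11.4 CPM against 104 ± 6.03 CPM (adjusted p = 0.592). Cyp26a1 fell to 77.1 ± 17.7 CPM from 538 ± 17.2 CPM (log2FC -2.80 ± 0.29, adjusted p = 0.00209), and Cyp26b1 to 1.80 ± 0.15 CPM from 39.4 ± 1.10 CPM (log2FC -4.44 ± 0.47, adjusted p = 0.00101). Of 19 RA signalling and metabolism genes, 6 fell over all genes, and over the list alone 9 fell and 1 rose. The median was -0.93 (adjusted p = 0.000257, adjusted p = 0.272 with an estimated correlation). Of 12 Hoxa genes 4 fell over all genes and 6 over the list alone, among them Hoxa5 (-1.56) and Hotairm1 (-1.61), an antisense transcript of the cluster whose reads could not be told apart by strand. The median was -1.08 (adjusted p = 3.37e-06, adjusted p = 0.295 with an estimated correlation). Of 12 Hoxb genes, Hoxb6 (-3.29) and Hoxb9 (-1.31) fell and 4 fell over the list alone. The median was -1.50 (adjusted p = 0.000258, adjusted p = 0.472 with an estimated correlation). Hoxb1 (log2FC -1.56 ± 0.64, adjusted p = 0.272) and Rarb (-0.93, adjusted p = 0.131) did not pass. The caudal homeobox gene Cdx1 fell from 129.7 ± 4.86 to 33.3 ± 1.56 CPM (log2FC -1.96 ± 0.19), and Gbx2, a homeobox gene of naive cells and hindbrain, rose (1.67 ± 0.20).

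Formative and naive pluripotency genes were among the rises in Rxra-KO. Of 16 formative and primed genes, 5 rose over all genes, and over the list alone 8 rose and 1 fell. The median was 0.39 (adjusted p = 0.000232, adjusted p = 0.272 with an estimated correlation). They included the epiblast factors Foxd3 (10.6 ± 1.30 to 45.4 ± 13.2 CPM), Pou3f1 (1.55) and Nkx6-3 (1.99). Of 20 naive genes 5 rose over all genes and 7 over the list alone, among them Nr0b1 (1.04), Manba (0.80) and Klf5 (0.70). The median was 0.37 (adjusted p = 0.00932, adjusted p = 0.472 with an estimated correlation). The extraembryonic endoderm list had a median of 0.44, with 1 gene up over all genes, the matrix protein gene Sparc (0.62), and 6 up and 1 down over the list alone (adjusted p = 0.00568, and adjusted p = 0.442 with an estimated correlation). The imprinted list was called with a median of 0.61 (adjusted p = 0.0185, and adjusted p = 0.472 with an estimated correlation), although Grb10 fell again (log2FC -2.27 ± 0.23). The epithelial factor Grhl2 (2.33 ± 0.30), Mt3 (2.81), Dok2 (5.27 to 29.7 CPM), Nap1l5 (2.44) and Gpx2 (2.34) had the largest rises, and after Cyp26b1 the largest falls were those of Zfp703 (-3.71 ± 0.43), Hoxb6, Fhad1 (-3.29) and Cdh22 (-3.15). In all, 407 genes changed, 210 up and 197 down, and 170 up and 258 down when libraries were scaled by their totals only. The count was 73 or 21 without WT replicate 1 or 2, and 361 or 149 without Rxra-KO replicate 1 or 2. Replicate 2 of Rxra-KO had a chromosome 16 median of 0.179 and replicate 1 of -0.016, with 6 rises and 0 falls called there, and 18 genes higher and 2 lower than in Rara-KO. On chromosome 2 there were 7 rises and 53 falls and on chromosome 10 there were 44 and 5, and the count was 219 with chromosomes 2, 6, 8, 10, 16 and Y left out. Between 160 and 180 Mb of chromosome 2, where Cdh22 lies, library medians were -0.419 and -0.319 in Rxra-KO and 0.071 and 0.136 in WT. Cyp26a1, Cyp26b1, Hotairm1, Cdx1, Gbx2 and Grb10 kept their calls with each library left out. The count was 639 by DESeq2, 1084 without the filter and 225 at 2-fold or more.

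In RARX-DKO cells, which lack both receptors by their labels, the RA-degrading enzymes and 10 of 20 extraembryonic endoderm genes fell. Rara fell to 5.57 and 6.53 CPM (log2FC -4.11 ± 0.19, adjusted p = 1.58e-07), and Rxra stood at 13.6 and 27.6 CPM against 42.1 ± 5.49 CPM in WT and did not pass (-1.04 ± 0.26, adjusted p = 0.0654). Cyp26a1 fell from 538 ± 17.2 to 26.5 ± 1.17 CPM (log2FC -4.34 ± 0.32, adjusted p = 0.000179), Cyp26c1 from 13.9 ± 0.59 to 1.15 ± 0.47 CPM (-3.56 ± 0.44) and Cyp26b1 from 39.4 ± 1.10 to 3.21 ± 0.85 CPM (-3.62 ± 0.43). Hoxb1 fell (log2FC -3.75 ± 0.77, adjusted p = 0.0423), a call lost without either of 2 of the 4 libraries. Of 20 extraembryonic endoderm genes, 10 fell over all genes, and over the list alone 13 fell and 1 rose. The median was -1.22 (adjusted p = 2.31e-11, adjusted p = 0.118 with an estimated correlation). Gata4 (10.8 ± 0.15 to 2.11 ± 0.092 CPM, log2FC -2.35 ± 0.33) and Gata6 (-1.93 ± 0.18), both transcription factors of primitive endoderm, and the endocytic receptor Cubn (-2.14) were among them. Of 20 naive genes 3 rose over all genes and 12 over the list alone, including Zfp42, a marker of undifferentiated cells (370.3 ± 1.75 to 817 ± 44.1 CPM, log2FC 1.14 ± 0.14), Manba (1.10) and Sox2 (0.97). The median was 0.54 (adjusted p = 4.05e-06, adjusted p = 0.301 with an estimated correlation). Of 12 Hoxb genes, Hoxb1, Hoxb6 and Hoxb9 fell over all genes and 9 over the list alone. The median was -1.84 (adjusted p = 1.62e-08, adjusted p = 0.301 with an estimated correlation). Of 12 Hox cofactor and Cdx genes, 4 fell over all genes and 6 over the list alone, with Meis1 (log2FC -2.21 ± 0.30) and Cdx1 (-1.17) among them (adjusted p = 0.00101, and adjusted p = 0.12 with an estimated correlation).

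The RA signalling list in RARX-DKO had 6 falls over all genes, and over the list alone 8 falls and 1 rise (adjusted p = 7.48e-07, and adjusted p = 0.118 with an estimated correlation). The Hoxa list had 4 falls over all genes, including Hoxa5 (-1.56), Hoxa4 (-1.48) and Hotairm1 (-1.43), and was not called (adjusted p = 0.0993). The p53 target list was not called either (adjusted p = 0.267), though the cell cycle inhibitor Cdkn1a rose (0.91). Nodal (0.91), a signal of the primitive streak, and Thy1 (2.05) rose, and Grb10 (-2.64 ± 0.23) and the growth factor gene Igf2 (-2.42) fell. The list of 16 genes around Cyp26a1 on chromosome 19 was called lower, with a median of -0.25 (adjusted p = 0.00223, adjusted p = 0.12 with an estimated correlation). So was that of 20 genes around Hoxb on chromosome 11, at -0.27 (adjusted p = 0.00365, adjusted p = 0.301 with an estimated correlation). Cholesterol synthesis genes (20) were called lower at -0.17 (adjusted p = 0.00223, adjusted p = 0.301 with an estimated correlation). Over all genes these lists held 2, 0 and 0 falls, and over the list alone 3, 2 and 3. The same Y-linked genes had 0 counts, with Eif2s3y and Ddx3y at least 287- and 236-fold lower. The largest rises were in Slc13a5 (2.99), Cdh3 (2.69 ± 0.33), Mt3 (2.61), Trp53tg5 (2.48) and Nrk (2.40). In all, 368 genes changed, 173 up and 195 down. On chromosome 2 there were 11 rises and 51 falls and on chromosome 10, which holds Nodal, there were 52 and 2, and the count was 161 with chromosomes 2, 6, 8, 10, 16 and Y left out. Genes on chromosome 8 had a median log2 deviation of 0.35 in RARX-DKO replicate 2 and -0.06 in replicate 1, and the count was 255 or 408 without RARX-DKO replicate 1 or 2. It was 53 or 32 without WT replicate 1 or 2, 570 by DESeq2, 981 without the filter and 191 at 2-fold or more. Rara, Cyp26a1, Cyp26b1, Cyp26c1, Hotairm1, Zfp42, Manba, Gata6 and Grb10 kept their calls with each library left out.

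**Figure D2:**
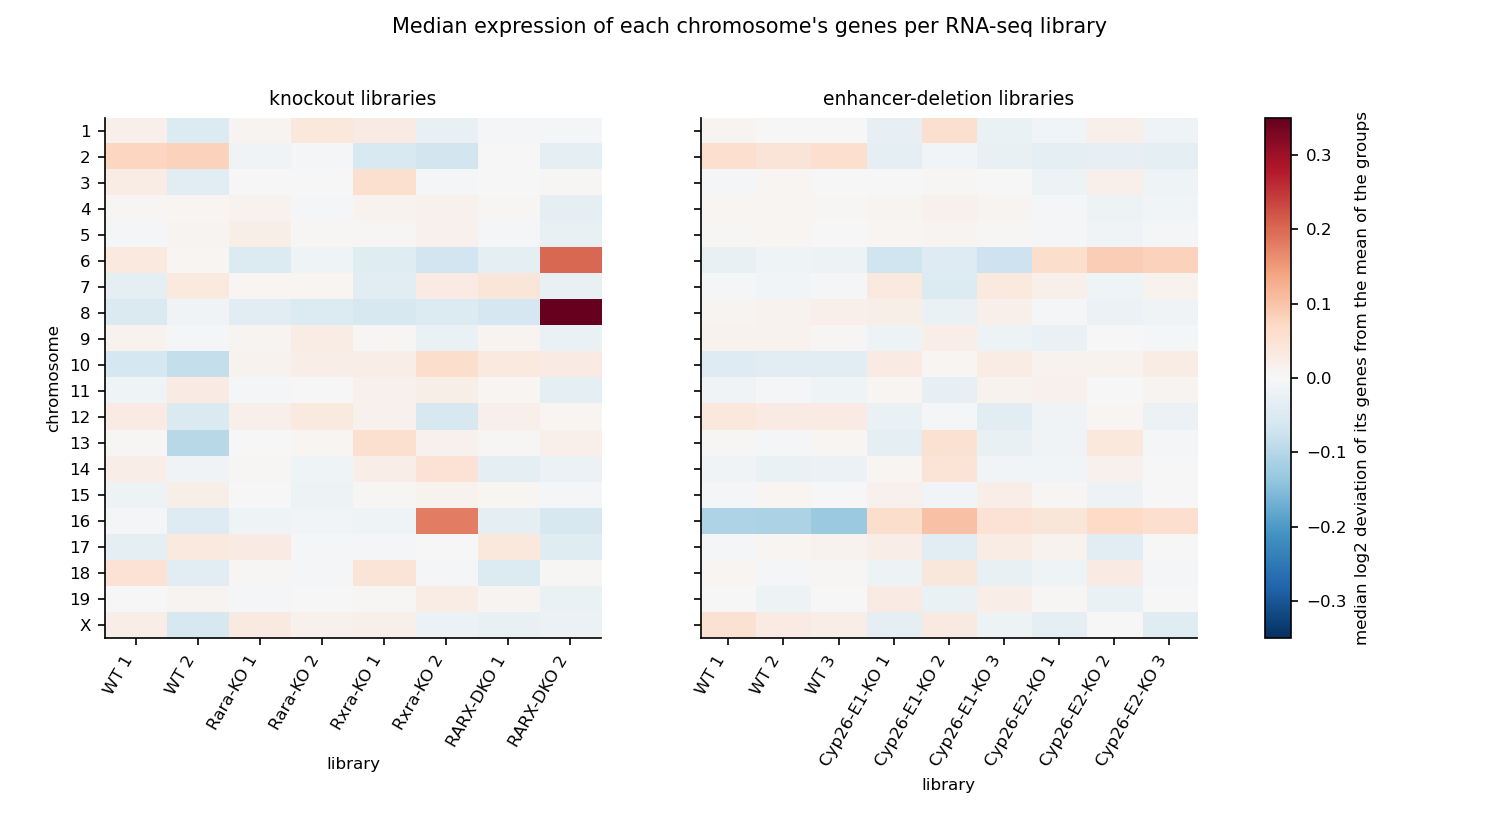
Median log2 deviation (colour) of the genes of each chromosome (y axis) from the mean of the group means, in every library of the knockout and enhancer tables (x axis). RARX-DKO replicate 2 reached 0.35 on chromosome 8 and 0.20 on chromosome 6, where replicate 1 had -0.06 on chromosome 8.

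The knockouts were compared for shared calls. In parts of chromosomes 2 and 10 WT lay apart from all 3. Library medians between 140 and 160 Mb of chromosome 2 were 0.315 and 0.38 in WT and -0.151 to -0.089 in the knockouts, and between 40 and 60 Mb of chromosome 10 they were -0.466 and -0.506 against 0 to 0.233. Rara-KO and RARX-DKO had 52 rises and 37 falls in common (0.67 and 0.50 for independent lists), with a covariance of log2FC of 0.246 against 0.0616 for simulated unchanged groups with the same WT libraries. Their correlation across genes was 0.777 against 0.475. Rara-KO replicate 2 and RARX-DKO replicate 1 lay closer, at 4.9 times the counting variance, than any replicates of this table (7.54 to 13.83 times). Rxra-KO and RARX-DKO shared 53 rises and 53 falls (2.21 and 2.34 for independent lists), with a covariance of 0.113 against 0.0617 and a correlation of 0.322 against 0.467. Rara-KO and Rxra-KO shared 20 rises and 8 falls (0.82 and 0.50), with a covariance of 0.0507 against 0.0614 and a correlation of 0.161 against 0.471. Simulated groups shared on average 0.25, 0.3 and 0.3 calls in the same direction for these pairs. The covariance of Rara-KO with Rxra-KO lay below its simulated value. With chromosomes 2, 6, 8, 10, 16 and Y left out, shared rises and falls were 13 and 12 for Rara-KO and RARX-DKO (0.081 and 0.097 for independent lists), 18 and 30 for Rxra-KO and RARX-DKO (0.56 and 0.86) and 1 and 4 for Rara-KO and Rxra-KO (0.15 and 0.10). For all pairs part of the shared calls may come from the common WT libraries, which are too few to be split, and genes are not independent replicates. In the direct comparison of Rxra-KO with Rara-KO, Hoxa9, Cdx1 and Nanog were lower in Rxra-KO. Hoxa9 stood at 1.41 ± 0.52 CPM in Rxra-KO and 14.7 ± 6.24 CPM in Rara-KO (log2FC -3.37 ± 0.48, adjusted p = 0.00321), and Nanog differed by -1.44 ± 0.18 (adjusted p = 0.00127). Cyp26a1 (-1.45 ± 0.28, adjusted p = 0.0204) and Cyp26b1 (-2.73, adjusted p = 0.00921) were lower in Rxra-KO, calls lost without any of 3 of the 4 libraries. Rara and Rxra differed by 4.23 and -1.40, and Hoxb1 (0.86, adjusted p = 0.529) and Rarb (-0.86, adjusted p = 0.115) did not differ past the threshold.

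Of 20 extraembryonic endoderm genes 10 were higher in Rxra-KO than in Rara-KO, and over the list alone 14 were higher and 1 lower, including Sox17 (2.20), an endoderm factor. The median was 0.89 (adjusted p = 3.7e-08, adjusted p = 0.266 with an estimated correlation). Formative genes had 5 higher over all genes and 8 over the list alone, with Sox3 at 1.91 and the epiblast factor Otx2 at 4.18 ± 0.80 (list adjusted p = 0.000835, adjusted p = 0.268 with an estimated correlation). The Otx2 call was lost without any of 3 of the 4 libraries. The Hoxa list had 5 lower members over all genes and 9 over the list alone (adjusted p = 1.95e-06, and adjusted p = 0.3 with an estimated correlation). Lists of germline genes (adjusted p = 0.0115, and adjusted p = 0.479 with an estimated correlation) and of fibroblast genes that mark feeder cells (7 genes, median -1.44, adjusted p = 0.00136, and adjusted p = 0.443 with an estimated correlation) were lower. Of these, 2 and 1 were lower over all genes, and 5 and 5 over the list alone. The imprinted list was higher (adjusted p = 0.0238, and adjusted p = 0.529 with an estimated correlation), with the retrotransposon-derived gene Peg10 at 1.70. Kif17 (-4.08), Peg12 (-3.89) and Fhad1 (-3.88) were among the largest differences, with the 5 Y-linked genes. In all 885 genes differed, 360 higher and 525 lower in Rxra-KO, and 254 and 731 when scaled by library totals, which shifted the median of all genes by -0.10. On chromosome 2, 23 were higher and 72 lower. The count was 478 or 111 without Rara-KO replicate 1 or 2, 648 or 415 without Rxra-KO replicate 1 or 2, 1840 without the filter and 585 at 2-fold or more. Whether the combined knockout departed from the sum of the log2FC of its parts was tested as an interaction. EdgeR called 0 of 16445 genes (1083 at an unadjusted p under 0.05, 40 by DESeq2, 115 without the filter). Cyp26a1 was at -0.18 ± 0.40 (adjusted p = 0.98), Hoxb1 at 0.23 ± 1.11 (adjusted p = 0.994) and Rarb at 0.69 (adjusted p = 0.874).

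Overexpressing Rara raised the RA-degrading enzymes and genes of extraembryonic lineages. Rara rose to 104.5 and 111 CPM from 51.6 and 52.4 CPM in V-OE (log2FC 1.05 ± 0.07, adjusted p = 2.36e-17), and Rxra stayed within the spread of the control (-0.01, adjusted p = 0.937). Cyp26a1 rose from 185 ± 1.19 to 535 ± 8.82 CPM (log2FC 1.53 ± 0.04, adjusted p = 1.26e-35), and Cyp26c1 by 1.65 ± 0.16. Hoxb1 rose from 1.12 ± 0.29 to 4.11 ± 1.29 CPM (1.91 ± 0.36, adjusted p = 2.39e-05), and Rarb did not pass (0.28, adjusted p = 0.0536). Of 20 extraembryonic endoderm genes, 18 rose over all genes and 18 over the list alone, with a list median of 2.17 (adjusted p = 2.47e-15, and adjusted p = 0.0599 with an estimated correlation). Gata4 rose from 3.16 ± 0.14 to 36.1 ± 1.23 CPM (log2FC 3.51 ± 0.16), Cubn by 3.95 and Foxq1 by 3.44. Of 16 trophectoderm genes, 11 rose over all genes and 12 over the list alone, including the simple-epithelium keratins Krt18 (15.1 ± 1.24 to 217 ± 1.70 CPM), Krt7 and Krt8. The median was 1.08 (adjusted p = 8.24e-07, adjusted p = 0.109 with an estimated correlation). The imprinted RNA H19 rose from 44.2 ± 4.58 to 969 ± 2.91 CPM (log2FC 4.46 ± 0.05), with its neighbour Igf2 (3.39). Naive and formative lists were lower. Of 22 naive genes 13 fell and 6 rose over all genes (14 and 6 over the list alone, adjusted p = 0.00249, and adjusted p = 0.163 with an estimated correlation), with Manba at -2.03. Of 14 formative genes 11 fell and 1 rose (11 and 2 over the list alone, adjusted p = 0.00057, and adjusted p = 0.163 with an estimated correlation), with Fgf15 at -2.04 and Zic2 at -1.06.

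Some Hox genes also rose in Rara-OE. In the Hoxb list 6 of 11 genes rose over all genes and over the list alone, with Hoxb3 at 2.34. The median was 1.25 (adjusted p = 0.000538, adjusted p = 0.163 with an estimated correlation). In the Hoxa list 4 of 12 rose on both counts (0.22, adjusted p = 0.0153, and adjusted p = 0.163 with an estimated correlation). Hoxc and Hoxd genes had 2 of 10 risen on both counts, including Hoxc4 (1.34) (adjusted p = 0.025, and adjusted p = 0.163 with an estimated correlation). The cofactor list 5 risen and 1 fallen on both, with Meis1 at 1.25 and Gbx2 at -1.02 (adjusted p = 0.0283, and adjusted p = 0.163 with an estimated correlation). The RA signalling list had 11 rises and 2 falls over all genes, and 13 and 2 over the list alone (median 0.61, adjusted p = 0.00034, and adjusted p = 0.149 with an estimated correlation). The 2-cell-like list, whose Zscan4 members share near-identical sequence and are therefore uncertain, was lower, with 3 of 9 fallen on both counts (adjusted p = 0.00434, and adjusted p = 0.163 with an estimated correlation). Neural Tubb3 fell (-1.46) within a neuroectoderm list that was not called (adjusted p = 0.639), and the angiogenic factor Vegfa rose (1.04) within a glycolysis and hypoxia list that was not called (adjusted p = 0.633). Other large changes were the rises of Zfp36l3 (4.15) and of C3ar1, which had 0 counts in V-OE and was at least 11.8-fold higher, and the falls of Wdr20rt (-2.52), Cox20 (-2.41), Notch4 (-2.39) and Hrh3 (-2.37). In all 4829 of 16914 genes changed, 2482 up and 2347 down, against 2416 by DESeq2 and 903 at 2-fold or more.

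Overexpressing Rxra gave the widest change of the series, with strong falls of pluripotency genes. Rxra rose to 202 and 204 CPM from 45.7 and 42.9 CPM (log2FC 2.20 ± 0.07, adjusted p = 9.89e-34), and Rara stood at 53.1 ± 2.97 CPM against 52.0 ± 0.59 CPM (adjusted p = 0.805). Cyp26a1 rose from 185 ± 1.19 to 1092 ± 5.66 CPM (log2FC 2.56 ± 0.04, adjusted p = 3.6e-47), Cyp26b1 from 21.6 ± 4.77 to 400.3 ± 13.3 CPM (4.22 ± 0.07, adjusted p = 1.62e-36) and Cyp26c1 by 3.17 ± 0.14. Sox2, a core pluripotency factor, fell from 384 ± 14.02 to 22.7 ± 0.67 CPM (-4.08 ± 0.06, adjusted p = 1.91e-48), and Tcl1 (-4.80) and Prdm14 (-4.02) fell with it. Of 22 naive genes, 18 fell over all genes and over the list alone. The median was -2.02 (adjusted p = 1.09e-09, adjusted p = 0.0637 with an estimated correlation). Of 14 formative genes 12 fell and 2 rose on both counts, with Foxd3 at -4.39, Pou3f1 at -4.27 and Zic2 at -3.32. The median was -2.18 (adjusted p = 5.5e-05, adjusted p = 0.137 with an estimated correlation). Of 20 extraembryonic endoderm genes, 19 rose over all genes, and over the list alone 19 rose and 1 fell, with Srgn at 5.27, Sox17 at 4.39 and Foxa2 at 3.95. The median was 2.44 (adjusted p = 1.81e-09, adjusted p = 0.0637 with an estimated correlation). Of 20 RA signalling genes 15 rose and 1 fell on both counts, including the carrier protein gene Crabp2 (3.51) and the receptor Rarb (1.31 ± 0.10, adjusted p = 7.46e-17). The median was 1.25 (adjusted p = 2.16e-05, adjusted p = 0.103 with an estimated correlation).

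In the Hoxb list of Rxra-OE 10 of 11 genes rose on both counts, with Hoxb3 at 3.51, Hoxb1 at 3.25 ± 0.30 and Hoxb13 at 3.02. The median was 2.32 (adjusted p = 0.000414, adjusted p = 0.137 with an estimated correlation). Of 10 Hoxc and Hoxd genes 9 rose, with 9 up and 1 down over the list alone (adjusted p = 0.00326, and adjusted p = 0.137 with an estimated correlation). The Hoxa list was not called (adjusted p = 0.984, median 0.01 but mean -0.04), with 4 genes up and 3 down on both counts. The cofactor list had 7 rises and 1 fall over all genes, 8 and 2 over the list alone, with Cdx2 (4.77), Meis1 (2.41) and Tshz1 (2.28) up (adjusted p = 0.0109, and adjusted p = 0.137 with an estimated correlation). Of 15 p53 targets 11 rose and 2 fell on both counts, including Phlda3 (1.34) (adjusted p = 0.0101, and adjusted p = 0.137 with an estimated correlation). Of 20 glycolysis and hypoxia genes 13 fell and 3 rose (14 and 3 over the list alone), including Ndrg1 (-1.70), Aldoa (-1.34) and Pfkp (-1.08) (adjusted p = 0.00612, and adjusted p = 0.137 with an estimated correlation). The 2-cell-like list rose with 6 members up and 1 down, 7 and 1 over the list alone, with the same doubt about Zscan4 copies (adjusted p = 0.0276, and adjusted p = 0.184 with an estimated correlation). The imprinted list was higher, with 13 up and 5 down on both counts and H19 (5.28) and Meg3 (4.34) among them (adjusted p = 0.0352, and adjusted p = 0.176 with an estimated correlation). Trophectoderm genes (7 up, 3 down, adjusted p = 0.113), neuroectoderm (5 up, 3 down, adjusted p = 0.408), mesoderm (5 up, 6 down, adjusted p = 0.705, median -0.42 but mean 0.55), germline (adjusted p = 0.408) and fibroblast genes (adjusted p = 0.414) were not called as lists. The meiotic cohesin gene Rec8 (2.63) rose and Tubb3 (-4.55) and the Notch ligand Dll1 (-3.63) fell. Lhx1 and C3ar1 had 0 counts in V-OE and were at least 44.8- and 20-fold higher, and Psca (7.92) and Ccdc42 (7.18) also rose. Pou4f2 had 0 counts in Rxra-OE and was at least 21.3-fold lower, and the activin subunit Inhbb (-6.71), Notch4 (-5.61) and Grm2 (-5.27) fell. In all 10178 genes changed, 5230 up and 4948 down, and 3505 changed at 2-fold or more. Scaling by library totals shifted the median of all genes by 0.10.

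Rxra-OE exceeded Rara-OE in the RA-degrading enzymes and in its effect on pluripotency genes. Against V-OE, Rxra rose more in Rxra-OE than Rara did in Rara-OE, so the overexpressions were not matched in level. The comparison therefore cannot separate the receptor from its level. Directly compared, Cyp26a1 was higher in Rxra-OE by 1.03 ± 0.04 (adjusted p = 8.15e-30), Cyp26b1 by 2.80 ± 0.06 (adjusted p = 5.98e-32), Rarb by 1.03 and Hoxb1 by 1.34 ± 0.24 (adjusted p = 3.47e-06). Sox2 was lower by -3.34 ± 0.06, and of 22 naive genes 20 were lower and 1 higher on both counts. The median was -1.76 (adjusted p = 6.91e-12, adjusted p = 0.0851 with an estimated correlation). RA signalling genes had 14 higher and 2 lower on both counts (adjusted p = 0.00039, and adjusted p = 0.126 with an estimated correlation). Of 10 Hoxc and Hoxd genes 9 were higher on both counts (adjusted p = 0.000969, and adjusted p = 0.126 with an estimated correlation). Of 9 2-cell-like genes 8 were higher and 1 lower on both counts, with Zscan4d at 3.59 (adjusted p = 0.000657, and adjusted p = 0.126 with an estimated correlation). Extraembryonic endoderm genes went both ways, 10 higher and 6 lower (10 and 8 over the list alone, adjusted p = 0.315), with the parathyroid hormone receptor gene Pth1r at 3.51. The comparison called 7979 genes, 4027 higher and 3952 lower, against 5013 by DESeq2 and 1974 at 2-fold or more. Against the vector, the overexpressions shared 2032 rises and 2005 falls (767.5 and 686.6 for independent lists, 0.7 calls on average in simulated unchanged groups), with 110 and 73 genes called in opposite directions. Their covariance was 0.477 against 0.0307 simulated and their correlation 0.709 against 0.503, and part of the excess may come from the shared V-OE libraries, which cannot be split.

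**Figure D3:**
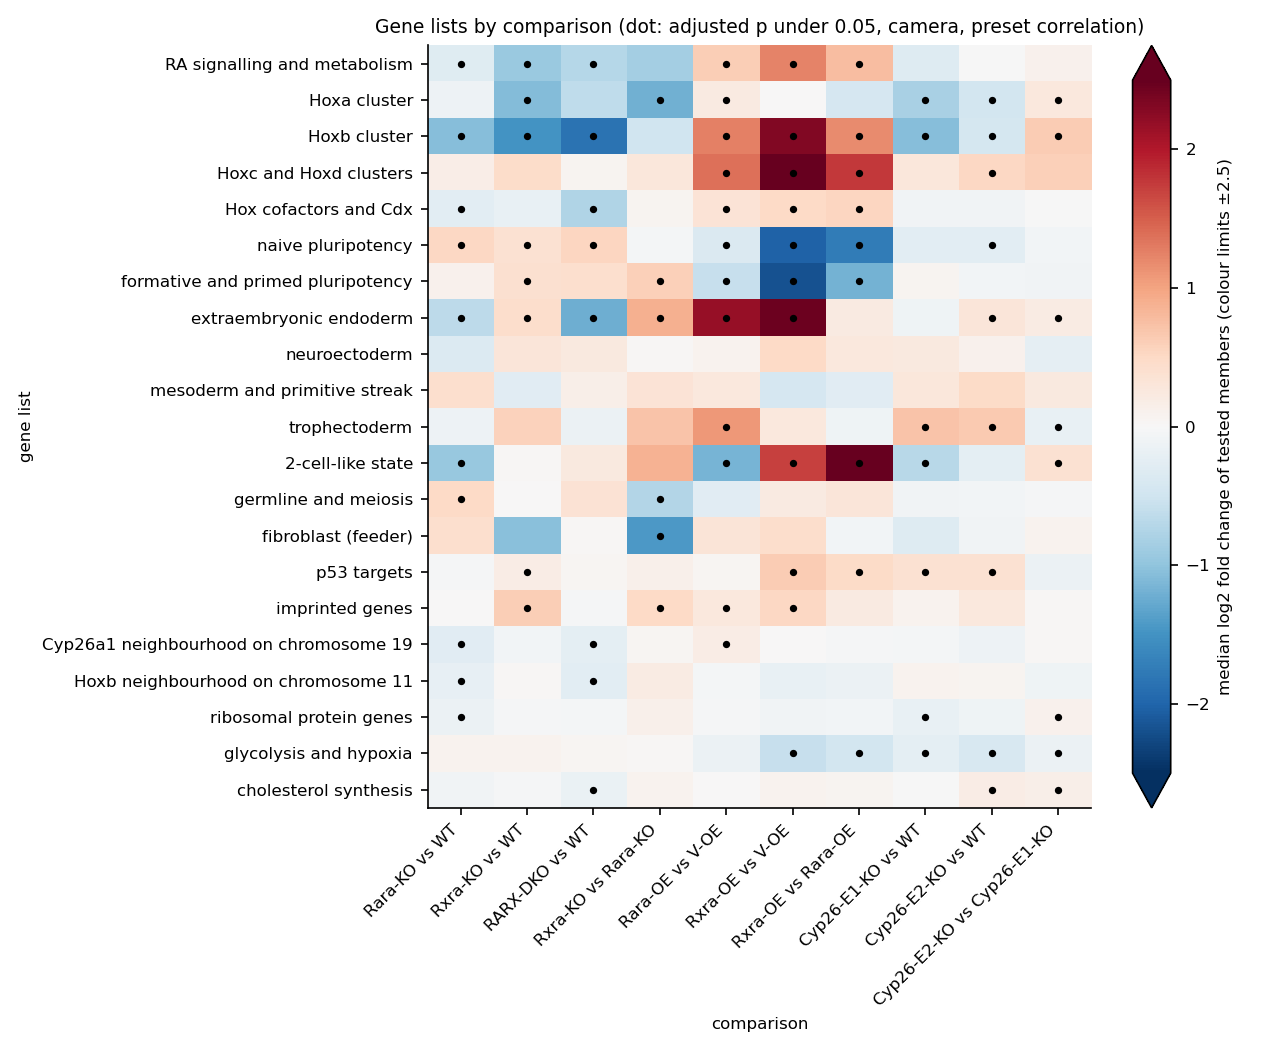
Median log2 fold change (colour) of the 21 gene lists (y axis) in 10 comparisons (x axis), with a dot where camera with its preset correlation gave an adjusted p under 0.05. The extraembryonic endoderm list ran from -1.22 in RARX-DKO to 2.44 in Rxra-OE.

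Deleting the Cyp26-E1 enhancer, whose bait lies at Cyp26a1 and Cyp26c1 on chromosome 19, lowered both genes and many Hox genes. Cyp26a1 (37697798 to 37701536) fell from 377 ± 8.80 CPM in WT to 49.5 ± 13.7 CPM (55.9, 33.8 and 58.8 CPM in the 3 libraries; log2FC -2.93 ± 0.18, adjusted p = 2.26e-06), and Cyp26c1 from 14.5 ± 3.16 to 1.41 ± 0.57 CPM (-3.36 ± 0.25, adjusted p = 5.87e-07). Cyp26b1 on chromosome 6, chosen after its values were seen, fell by less (-0.32 ± 0.07, adjusted p = 0.00382). Hoxb1 fell from 66.8 ± 2.35 to 22.9 ± 1.16 CPM (-1.54 ± 0.08, adjusted p = 1.73e-08). Of 12 Hoxb genes 9 fell over all genes and 10 over the list alone, with Hoxb6 at -1.68 and Hoxb5 at -1.64. The median was -1.06 (adjusted p = 3.06e-07, adjusted p = 0.283 with an estimated correlation). Of 11 Hoxa genes 9 fell on both counts. The median was -0.82 (adjusted p = 1.38e-05, adjusted p = 0.321 with an estimated correlation). Rara fell (-0.54 ± 0.07, adjusted p = 9.53e-05), Rxra rose slightly (0.28, adjusted p = 0.0182; the call was lost without either of 2 of the 6 libraries) and Rarb did not pass (-0.12, adjusted p = 0.549). The Nodal inhibitors Lefty2 (73.6 ± 2.04 to 3.03 ± 0.36 CPM, log2FC -4.60 ± 0.11, adjusted p = 7.72e-12) and Lefty1 (-2.81 ± 0.10, adjusted p = 8.23e-10) fell, with Ndufa4l2 (-5.20), the endoderm factor Hnf4a (-3.63) and the meiotic kinase gene Aurkc (-3.38). The T-box gene Tbx18 (3.87 ± 0.24), the natriuretic peptide receptor Npr3 (3.40), Pcdh17 (3.09), Pcdh10 (2.72) and Sema3d (2.57) had the largest rises.

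Of 16 trophectoderm genes, 9 rose on both counts after Cyp26-E1 deletion, including Hand1 (2.35) and Gata3 (2.21). The median was 0.72 (adjusted p = 2.67e-05, adjusted p = 0.142 with an estimated correlation). Of 14 p53 targets 8 rose over all genes and 9 over the list alone, with Mdm2 at 0.67 (adjusted p = 0.000456, and adjusted p = 0.139 with an estimated correlation). Of 20 glycolysis and hypoxia genes 12 fell over all genes and 13 over the list alone, with Pfkp at -1.19 and Vegfa at -1.03 (adjusted p = 1.38e-05, and adjusted p = 0.142 with an estimated correlation). Of 14 2-cell-like genes 9 fell on both counts (adjusted p = 0.000188, and adjusted p = 0.321 with an estimated correlation). The 23 ribosomal protein genes had a median of -0.19, with 4 falls over all genes and 1 over the list alone (adjusted p = 0.00608, and adjusted p = 0.626 with an estimated correlation). The RA signalling list was not called (3 up and 9 down over all genes, 5 and 10 over the list alone, adjusted p = 0.0639). The naive list was not called (adjusted p = 0.0917), but Nanog (-0.96) fell and Nr0b1 (1.07) rose. Foxd3 (1.13) and Otx2 (0.90) rose in a formative list that was not called (adjusted p = 0.715). The neighbours of Cyp26a1 (3 up, 6 down, adjusted p = 0.19) and of Hoxb (adjusted p = 0.306) were not called. Of imprinted genes (adjusted p = 0.684) Plagl1 (-1.81) fell and Igf2 (0.94) rose. In all 4741 of 18768 genes changed, 2464 up and 2277 down, and 1043 at 2-fold or more. Cyp26-E1-KO replicate 2 had 2.83% mitochondrial counts against 1.92% and 1.87% in the other two.

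Deleting the Cyp26-E2 enhancer, whose bait lies on chromosome 6 near Cyp26b1, lowered Cyp26b1 and left Cyp26a1 near its WT level. Cyp26b1 (84571414 to 84593908) fell from 80.8 ± 2.98 to 17.8 ± 0.88 CPM (17.2, 17.4 and 18.8 CPM in the 3 libraries; log2FC -2.18 ± 0.07, adjusted p = 8.96e-10). Cyp26a1 stood at 380.3 ± 15.2 CPM against 377 ± 8.80 CPM (0.01 ± 0.16, adjusted p = 0.975) and Cyp26c1 at 11.6 ± 1.59 CPM (adjusted p = 0.329). Hoxb1 fell from 66.8 ± 2.35 to 41.2 ± 2.16 CPM (-0.70 ± 0.08, adjusted p = 2.83e-05). Of 12 Hoxb genes 5 fell over all genes and 7 over the list alone. The median was -0.43 (adjusted p = 0.000389, adjusted p = 0.313 with an estimated correlation). Of 11 Hoxa genes 4 fell and 1 rose, 6 and 1 over the list alone (-0.45, adjusted p = 0.00178, and adjusted p = 0.356 with an estimated correlation). Hoxc and Hoxd genes had 3 of 11 risen over all genes and 5 over the list alone, with Hoxd8 at 2.02 and Hoxd13 at 0.96 (adjusted p = 0.00975, and adjusted p = 0.122 with an estimated correlation). Rdh10, which makes the RA precursor retinal, rose (0.95, adjusted p = 6.35e-05), and Rara fell (-0.40, adjusted p = 0.00176) while Rxra (0.13, adjusted p = 0.306) and Rarb (-0.00, adjusted p = 0.989) did not pass. The largest rises were those of Tbx18 (2.96), the ubiquitin ligase adaptor gene Klhl13 (172 ± 3.33 to 750.3 ± 42.6 CPM, log2FC 2.13 ± 0.09), Pcdh17, Npr3 and Msc (1.87). The largest falls, with Cyp26b1, were those of Ndufa4l2 (-2.99), the opioid precursor gene Pdyn (-2.66), Chac1 (-2.52) and Ubap1l (-2.19). Of 20 glycolysis and hypoxia genes 14 fell over all genes and 16 over the list alone, with Vegfa down from 71.0 to 31.3 CPM, Ndrg1 at -1.12 and Pfkp at -1.07. The median was -0.39 (adjusted p = 9.99e-10, adjusted p = 0.0634 with an estimated correlation). Of 16 trophectoderm genes 8 rose over all genes and 9 over the list alone, with Hand1 at 1.59 and Gata3 at 1.57 (adjusted p = 0.0011, and adjusted p = 0.122 with an estimated correlation).

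In Cyp26-E2-KO 11 of 20 endoderm genes rose and 1 fell on both counts, with the adaptor gene Dab2 at 1.01 (list adjusted p = 0.00178, and adjusted p = 0.0634 with an estimated correlation). Of 22 naive genes 8 fell and 3 rose over all genes and 9 and 3 over the list alone, with Nanog at -0.66 and Klf2 at -0.58 (adjusted p = 0.00732, and adjusted p = 0.165 with an estimated correlation). Of 14 p53 targets 7 rose over all genes and 9 over the list alone, including Cdkn1a (0.78) (adjusted p = 0.0011, and adjusted p = 0.0634 with an estimated correlation). Of 20 cholesterol synthesis genes 8 rose over all genes and 9 over the list alone, including Insig1 (0.51) (adjusted p = 0.00425, and adjusted p = 0.367 with an estimated correlation). The mesoderm list was not called (adjusted p = 0.198), though the endothelial receptor Kdr rose (1.85) and Lefty2 fell (-1.11). In all 3280 genes changed, 1741 up and 1539 down, and 483 at 2-fold or more. The count was 5731 with WT and Cyp26-E2-KO alone in the fit, 2130, 2123 or 2099 without WT replicate 1, 2 or 3, and 2174 or 1978 without Cyp26-E2-KO replicate 1 or 3. Compared with WT, the deletions shared 1310 rises and 1101 falls (228.6 and 186.7 for independent lists, 0.15 in simulated unchanged groups), with 4 and 13 genes in opposite directions. Genes on chromosome 16 lay apart between WT (library medians of -0.109 to -0.130 in log2) and both deletions (0.043 to 0.102), with 157 rises and 37 falls there in Cyp26-E1-KO and 143 and 25 in Cyp26-E2-KO. So did those on chromosome 2 (0.046 to 0.059 in WT and -0.033 to -0.010 in the deletions, 154 rises and 266 falls in Cyp26-E1-KO and 97 and 214 in Cyp26-E2-KO) and chromosome 10 (-0.046 to -0.037 and 0.006 to 0.029, 150 and 99, and 112 and 50). With chromosomes 2, 6, 8, 10, 16 and Y left out the deletions shared 882 rises and 753 falls (142.8 and 121.4 for independent lists). The covariance of the deletions was 0.23 against 0.0461 simulated and their correlation 0.717 against 0.498, and part of the excess may come from the shared WT libraries, which cannot be split.

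The deletions differed from each other in the Cyp26 genes and the Lefty genes. Cyp26-E2-KO exceeded Cyp26-E1-KO in Cyp26a1 (log2FC 2.94 ± 0.18, adjusted p = 2.69e-05), Cyp26c1 (3.04 ± 0.25), Lefty2 (3.49 ± 0.11, adjusted p = 2.81e-10) and Lefty1 (2.44), and was lower in Cyp26b1 (-1.86 ± 0.07, adjusted p = 3.71e-09). Hoxb1 was higher by 0.85 ± 0.08 (adjusted p = 3.02e-05), with Hoxb2 (1.00) and Hoxb5 (0.88). Of 12 Hoxb genes 5 were higher over all genes and 8 over the list alone (adjusted p = 1.05e-07, and adjusted p = 0.243 with an estimated correlation). Of 20 endoderm genes 7 were higher, with 9 higher and 1 lower over the list alone, among them Srgn (2.02) and Hnf4a (1.92). This was the only list call of the series that held with an estimated correlation (adjusted p = 2.31e-05, and adjusted p = 0.0478 with an estimated correlation). Of 20 cholesterol synthesis genes 5 were higher over all genes and 7 over the list alone (adjusted p = 7.93e-06, and adjusted p = 0.243 with an estimated correlation). Npr3 (-1.37), Otx2 (-0.80), Ror1 (-1.20) and Cxcl12 (-1.17) were lower, and Stra8 (0.93), a meiotic gene induced by RA, and H19 (1.64) were higher. The ribosomal list was called higher (adjusted p = 0.0203, and adjusted p = 0.562 with an estimated correlation), with an adjusted p of 0.706 without Cyp26-E1-KO replicate 2. In all 842 genes differed, 380 higher and 462 lower, and 505 and 334 when scaled by library totals. Genes on chromosome 6 lay apart in every library (medians of -0.046 to -0.073 in Cyp26-E1-KO and 0.062 to 0.087 in Cyp26-E2-KO), and 69 were called higher and 13 lower there. The count was 1852 without Cyp26-E1-KO replicate 2, 400, 379 or 310 without Cyp26-E2-KO replicate 1, 2 or 3, 1289 by DESeq2, 1384 without the filter, 339 with these groups alone in the fit and 112 at 2-fold or more.

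From the Hoxb-E1 bait, Rara-KO libraries had fewer reads at Hoxb13 and Hoxb9 than WT. The bait window, inferred from the reads, covered Hoxb5 and the end of Hoxb6 (chromosome 11, 96300001 to 96310000, mm10), and libraries held 35201280 to 47639838 reads. In Rara-KO the window at Hoxb13 (96190001 to 96200000) fell from 2.495 ± 1.01% to 0.170 ± 0.013% of reads in the tested windows (log2FC -3.88 ± 0.90, adjusted p = 0.00344). Reads within 5 kb of the Hoxb9 start fell from 2.70 ± 1.50% to 0.833 ± 0.002% (-1.70 ± 0.62, adjusted p = 0.0167 over 5 gene regions only). No 10-kb window at Hoxb9 was called. Hoxb3 to Hoxb8 reached into the left-out region and were not tested. Without WT replicate 2 the Hoxb9 log2FC was -0.98, and its call was lost without any library other than WT replicate 1. A window within Skap1 (96500001 to 96510000) rose from 1.56 ± 0.39% to 5.59 ± 2.00% (1.84 ± 0.49, adjusted p = 0.0205), and the RARX-DKO libraries had 4.03% and 6.09% there. Fragments under 40 bp held 73.6% and 65.2% of the Rara-KO reads of this window and 27.3% and 77.9% of the WT reads. These calls rested on the reads, since counting covered fragments instead gave 0 windows and log2FC of 0.05 and 0.01 at Hoxb13 and Hoxb9. In the Hoxb13 window 15 to 20 fragments were covered in every library, while its reads ran from 17845 to 423237. Covered fragments could therefore hardly show a change there and do not speak against one. The count of 2 windows became 1, 0, 0 and 5 without WT replicate 1 or 2 and Rara-KO replicate 1 or 2, and 0 with 20-kb windows, 5-kb windows or TMM scaling. Hoxb1 itself did not differ in Rara-KO (-0.58, adjusted p = 0.484), Rxra-KO (0.16, adjusted p = 0.859) or RARX-DKO (-0.60, adjusted p = 0.586). Hoxb13 was at -1.81 (adjusted p = 0.151) in Rxra-KO and -1.23 (adjusted p = 0.586) in RARX-DKO, whose libraries had 1.99% and 0.142% there.

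From the Hoxb-E2 bait, in an annotated part of Skap1 (96580001 to 96590000), edgeR called 0 of 195 windows in Rara-KO, Rxra-KO and RARX-DKO, with 10, 1 and 13 at an unadjusted p under 0.05. Hoxb-E1 gave 0 of 196 windows in Rxra-KO and RARX-DKO, with 9 and 9 at an unadjusted p under 0.05. The count became 3 at Hoxb-E1 without RARX-DKO replicate 1 and 3 at Hoxb-E2 without Rara-KO replicate 1. Contacts of Hoxb-E2 with Hoxb1 had log2FC of 0.81 (adjusted p = 0.965), 0.20 (adjusted p = 0.997) and -0.03 (adjusted p = 0.97) in Rara-KO, Rxra-KO and RARX-DKO, and with Hoxb8 the RARX-DKO value was -1.77 (adjusted p = 0.102). These libraries held 3398112 to 42841488 reads. Simulated windows changed 4-fold were called in 0 of 20 cases at each Hoxb bait, so a lack of calls does not exclude changes of that size.

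**Figure D4:**
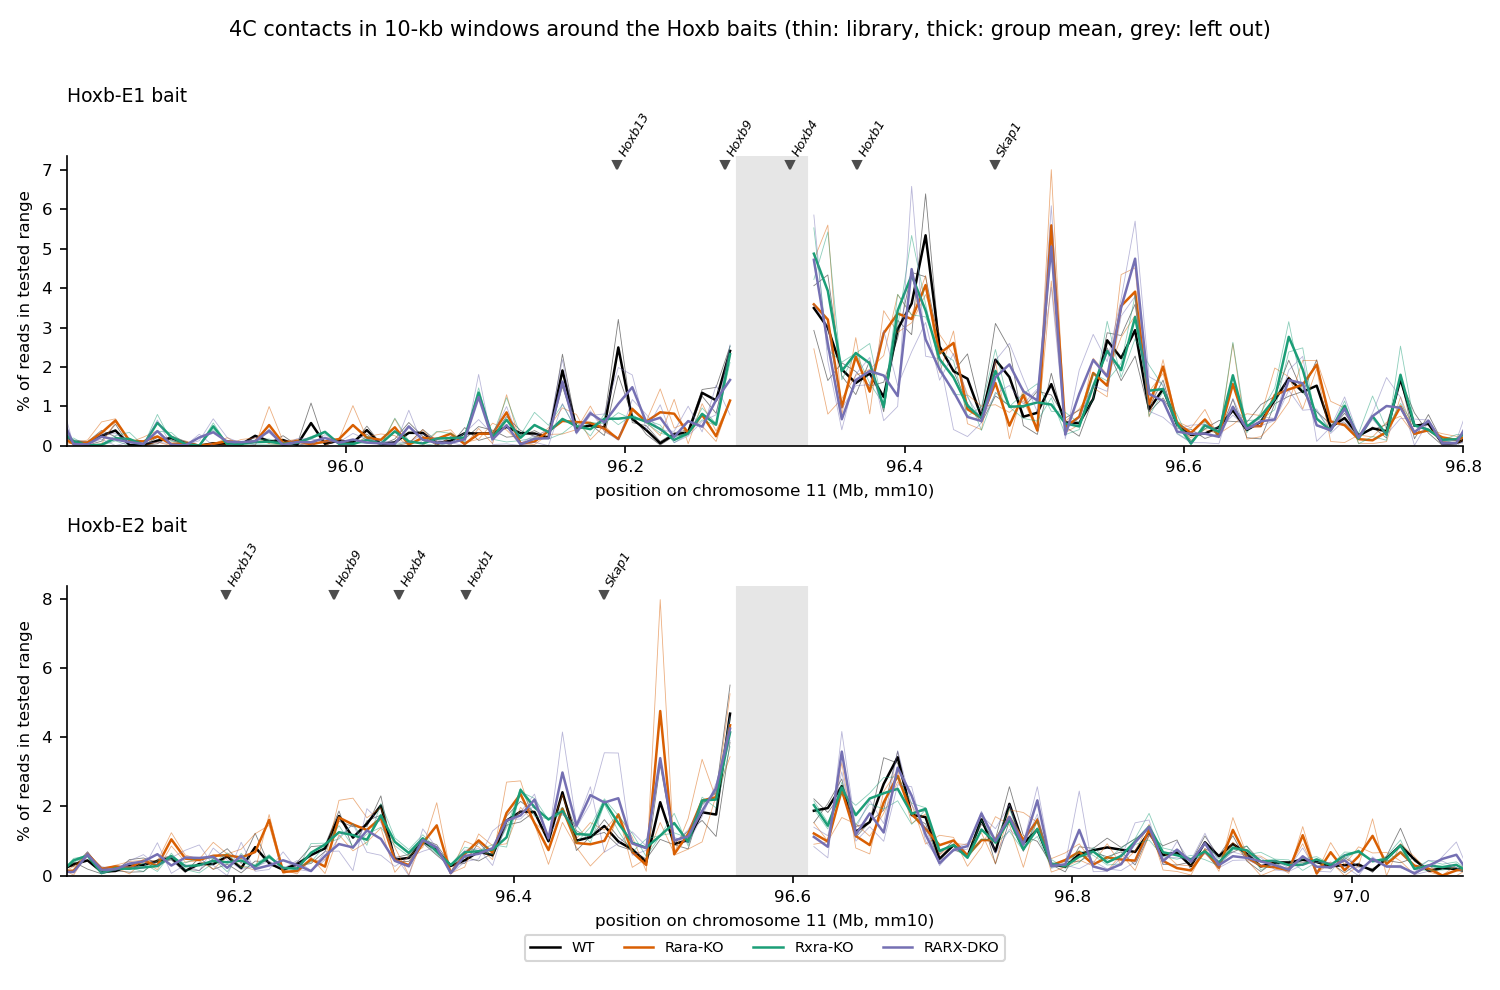
Percent of reads per 10-kb window (y axis) against position on chromosome 11 within 500 kb of the Hoxb-E1 and Hoxb-E2 baits (x axis), with thin lines for libraries, thick lines for genotype means and grey for the region left out around the bait. At Hoxb13 the Hoxb-E1 profile stood at 2.495% in WT and 0.170% in Rara-KO.

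The Cyp26 baits gave sparse profiles of 863 to 2664 covered fragments, against 31415 to 134799 for the Hoxb baits, and paired libraries shared 99.9% or more of their fragments. Tests at these baits therefore compare libraries, not genotypes, and no contact change is assigned to a genotype here. The Cyp26-E1 bait window (chromosome 19, 37690001 to 37700000) covered Cyp26a1 and Cyp26c1, and libraries held 585791 to 2747886 reads. Within the left-out region, reads at Cyp26a1 per 100 in the tested windows were 36.6 ± 1.47 in WT, 27.5 ± 0.63 in Rara-KO, 75.5 ± 0.89 in Rxra-KO and 14.1 ± 0.67 in RARX-DKO. Exoc6, the gene next to Cyp26c1, had 1.99 ± 0.009% of reads in WT, 0.168 ± 0.012% in Rara-KO, 1.41 ± 0.035% in Rxra-KO and 2.83 ± 0.091% in RARX-DKO. Rbp4, the gene of the plasma retinol carrier, had 0.0139% in WT, 0.256% in Rara-KO, 0.302% in Rxra-KO and 3.35% in RARX-DKO, and its Rara-KO log2FC of 4.22 turned to -8.72 with 2.5-kb flanks. Of 179 windows 161, 161 and 152 differed between the WT libraries and those of Rara-KO, Rxra-KO and RARX-DKO. A window at 37340001 to 37350000 had 0 reads in WT and 1.65 ± 0.034% in Rara-KO, and a window at 38230001 to 38240000 had 0.904 ± 0.076% in WT and 0 reads in RARX-DKO.

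The Cyp26-E2 bait window (chromosome 6, 84640001 to 84650000) lay in an intron of Exoc6b, close to Cyp26b1, and libraries held 3007960 to 10080430 reads. Cyp26b1, a gene added once the bait position was known, had 4.26 ± 0.20% of reads in WT, 1.84 ± 0.077% in Rara-KO (log2FC -1.21), 4.25% in the merged Rxra-KO pair (log2FC -0.00) and 2.14 ± 0.004% in RARX-DKO (log2FC -0.99). No p-value is given, since the merged pair is 1 sample without a spread of its own and the other pairs vary only between libraries that share nearly all fragments. Reads within 100 kb made up 31.9% and 32.4% in the WT libraries, 28.5% and 28.1% in Rara-KO, 27.4% in Rxra-KO and 17.3% and 17.1% in RARX-DKO. Against that spread 174 and 175 of 191 windows differed between the WT libraries and those of Rara-KO and RARX-DKO. The window at Cct7 and Fbxo41 (85460001 to 85470000) had 0 reads in WT and 0.0702%, 0.484% and 0.0762% in the knockouts, and a window at 84310001 to 84320000 had 0.985 ± 0.042% in WT and 0 reads in RARX-DKO.

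**Figure D5:**
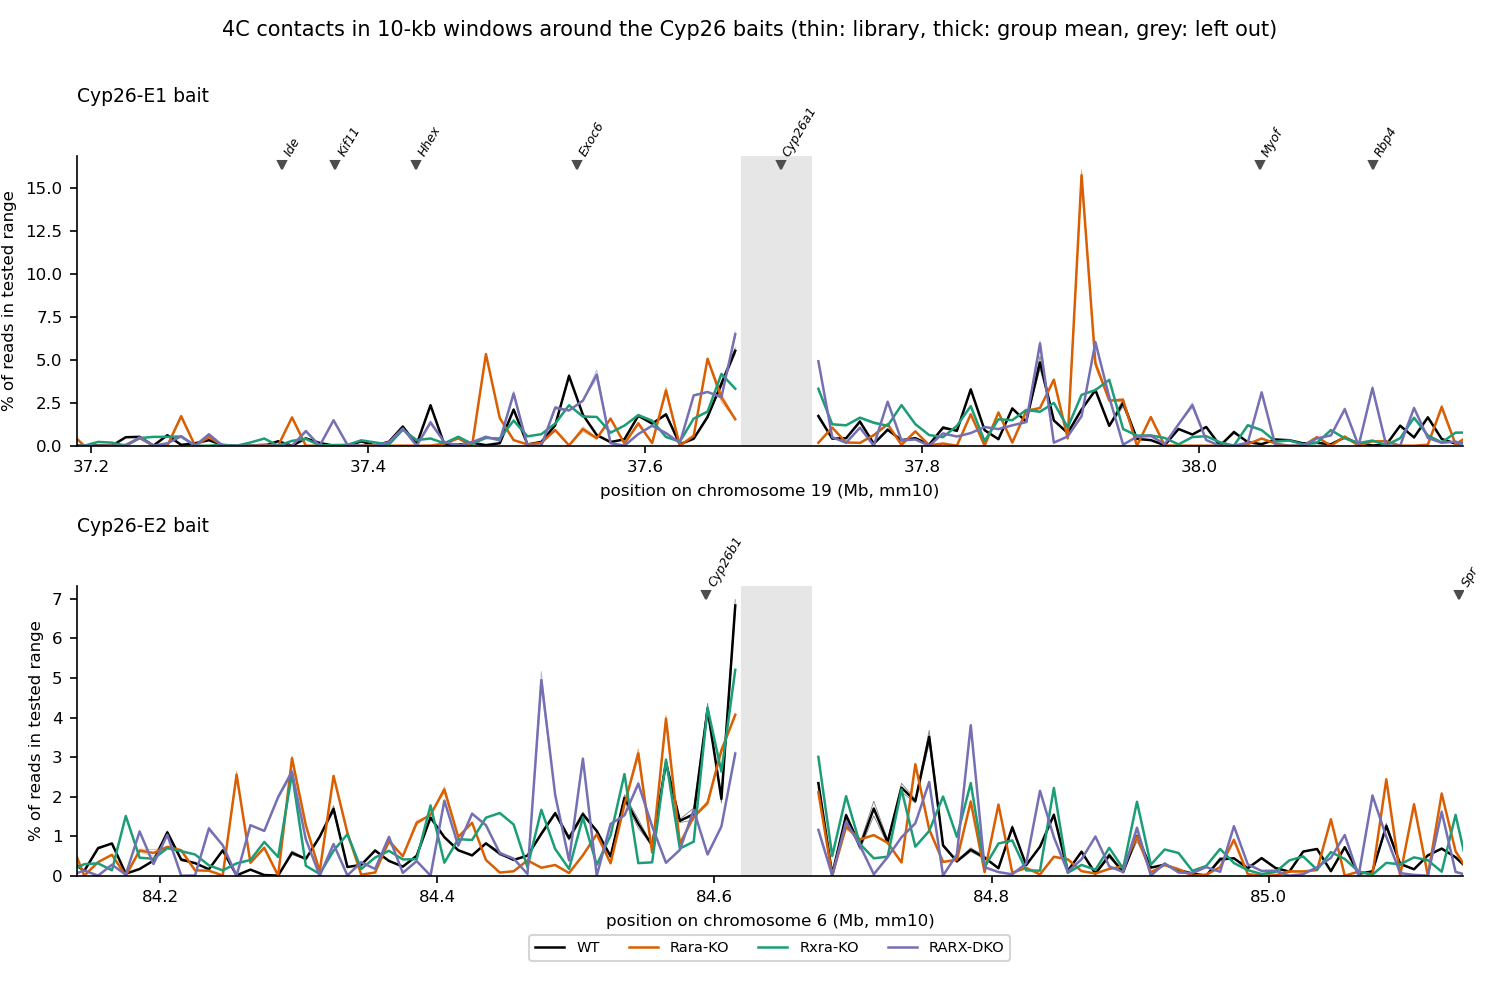
Percent of reads per 10-kb window (y axis) within 500 kb of the Cyp26-E1 bait on chromosome 19 and the Cyp26-E2 bait on chromosome 6 (x axis), with thin lines for libraries, thick lines for genotype means and grey for the region left out around the bait. Paired libraries overlie each other and share 99.9% or more of their fragments.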

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

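Leaving out 1 library of a group of 2 leaves its arm with 1 sample, which is then assumed to vary like the other groups. The cause of the moves below was not tested. Requiring a change of 2-fold or more left 55 genes in Rara-KO, 225 in Rxra-KO, 191 in RARX-DKO, 585 in Rxra-KO against Rara-KO, 903 in Rara-OE, 3505 in Rxra-OE, 1974 in Rxra-OE against Rara-OE, 1043 in Cyp26-E1-KO, 483 in Cyp26-E2-KO and 112 in Cyp26-E2-KO against Cyp26-E1-KO. Without the filter the counts were 551 in Rara-KO, 1084 in Rxra-KO, 981 in RARX-DKO, 1840 in Rxra-KO against Rara-KO, 115 in the interaction and 1384 in Cyp26-E2-KO against Cyp26-E1-KO. DESeq2 called 259 in Rara-KO, 639 in Rxra-KO, 570 in RARX-DKO, 40 in the interaction, 2416 in Rara-OE, 5013 in Rxra-OE against Rara-OE and 1289 in Cyp26-E2-KO against Cyp26-E1-KO. Fitting the compared groups alone gave 588 in Rara-KO, 5731 in Cyp26-E2-KO and 339 in Cyp26-E2-KO against Cyp26-E1-KO. Library totals alone gave 1 gene in the interaction. Of 88 list calls 1 held with an estimated correlation.

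Leaving out each library gave 8 to 29 genes in Rara-KO, 21 to 361 in Rxra-KO, 32 to 408 in RARX-DKO, 111 to 648 in Rxra-KO against Rara-KO, 0 to 17 in the interaction, 3728 to 3925 in Rara-OE, 8765 to 9214 in Rxra-OE, 6391 to 7019 in Rxra-OE against Rara-OE, 3413 to 6217 in Cyp26-E1-KO, 1978 to 2220 in Cyp26-E2-KO, 310 to 1852 in Cyp26-E2-KO against Cyp26-E1-KO and 85 to 94 gene lists. With all libraries there were 39 gene calls in 4C, of which 2 lay at a Hoxb bait, in Rara-KO at Hoxb-E1. The rest lay at the Cyp26 baits, those of the merged Rxra-KO pair among them. Paired libraries there share nearly all fragments, so leaving 1 out cannot test those calls. Changes at the Hoxb baits with a library left out are given with their results. List calls that turned were Hoxc with Hoxd in Rxra-KO (adjusted p = 0.0175 without Rxra-KO replicate 2, 0.806 with it, range 0.00705 to 0.891) and in Rxra-KO against Rara-KO (0.0204 against 0.985, range 0.0204 to 0.205), the 2-cell-like list in RARX-DKO (6.37e-06 without replicate 1 of RARX-DKO, 0.958 with it, range 6.37e-06 to 0.897), and ribosomal proteins in Cyp26-E2-KO against Cyp26-E1-KO (0.706 without Cyp26-E1-KO replicate 2, 0.0203 with it, range 0.000199 to 0.706).

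In 4C the 2 Hoxb-E1 windows of Rara-KO became 0 with 20-kb windows, 0 with 5-kb windows and 0 with TMM. They also became 0 with covered fragments in place of reads, which gave Hoxb13 0.054 by window and 0.095 by gene and Hoxb9 0.013. Covered fragments could hardly show a change at Hoxb13, where every library had 15 to 20 of them. In RARX-DKO Hoxb-E1 had 1 window within 500 kb, and Hoxb-E2 had 1 with 5-kb windows. Counts at the Cyp26 baits moved with the number of windows tested: at Cyp26-E1 20-kb windows gave 82, 81 and 83, 5-kb windows 257, 280 and 249, and the range within 500 kb 91, 85 and 86 in Rara-KO, Rxra-KO and RARX-DKO, and at Cyp26-E2 these were 85, 86 and 89, then 308, 313 and 304, then 85, 89 and 88. The middle count of each set at Cyp26-E2 is that of the merged Rxra-KO pair. That pair is 1 sample, so its counts use the spread of the other pairs and no conclusion is drawn from them. With 2.5 kb around gene starts Rbp4 in Rara-KO turned to -8.72, Exoc6 and Hhex in Rxra-KO to 0.40 and -0.13, Exoc6b in Rara-KO and Rxra-KO to -13.14 and -6.96, and Emx1 in Rxra-KO to 10.28.

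Replicates share only a number, which nothing in the labels ties to a common culture. With the number as a block, genes called were 86, 314, 296, 737 and 0 in the knockout table, 4559, 10005 and 7751 in the overexpression table and 4769, 3289 and 861 in the enhancer table, and Hoxb-E1 had 1 window in RARX-DKO. Residual correlation between same-numbered libraries ran from -0.214 to 0.121 in the knockout table, -0.014 to 0.007 in the overexpression table and -0.056 to 0.107 in the enhancer table. At Hoxb-E1 it ran from -0.027 to 0.2, with 3 of 6 pairs over 0.1, and libraries with the same number shared a median 41.95% of fragments, against 24.05% with another number and 28.5% in the same genotype. At Hoxb-E2 these shares were 23.5%, 16.9% and 17.55%. At Hoxb-E2, Cyp26-E1 and Cyp26-E2 it ran from -0.099 to 0.046, -0.117 to 0.067 and -0.125 to -0.035. Not every pair lay over 0.1 in any table, so the numbers were not taken as pairs, though fragment sharing ties them in part at both Hoxb baits. Leaving out genes on chromosomes 6, 8, 16 and Y gave 93, 354, 344, 814 and 0 genes in the knockout table and 4031, 2692 and 675 in the enhancer table. With chromosomes 2 and 10 left out as well these were 28, 219, 161, 639 and 0, and 3327, 2207 and 577, over 12310 and 13918 genes tested. The first 3 moved most, and of their main calls 21, 60 and 62 lay on chromosome 2 and 29, 49 and 54 on chromosome 10.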

Other observations

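Comparisons across the tables, which have separate controls, were chosen after the results were seen. In both tables the medians of chromosomes 2 and 10 set WT apart from Rxra-KO and the deletions, though the shift lay in parts of them. In the enhancer table, 140 to 160 Mb of chromosome 2 had 0.164 to 0.171 in WT and -0.094 to -0.063 in the deletions. Between 20 and 40 Mb these were -0.02 to 0.002 and -0.022 to 0.02. On chromosome 10, 40 to 60 Mb had -0.193 to -0.15 against 0.057 to 0.112. Medians over all of chromosome 2 were 0.076 and 0.082 in WT against -0.054 and -0.063 in Rxra-KO, and 0.046 to 0.059 in WT against -0.033 to -0.010 in the deletions. On chromosome 10 they were -0.062 and -0.083 against 0.024 and 0.061, and -0.046 to -0.037 against 0.006 to 0.029. Why both WT groups differ there was not tested. Rxra-KO shared more changes with the enhancer deletions than independent lists would, with these chromosomes or without. With Cyp26-E1-KO it had 128 rises and 131 falls in common (30.6 and 27.4 for independent lists), and 11 and 9 genes in opposite directions (29.1 and 28.8). Genes lower in both included Cyp26a1, Cyp26c1 and Cdx1, which were picked after the results were seen. With Cyp26-E2-KO there were 113 rises and 113 falls in common (21.9 and 19.2), and Cyp26b1 and Cdx1 were lower in both. Correlations of log2 fold changes across 14944 genes were 0.33 and 0.357, and genes are not independent replicates. With chromosomes 2, 6, 8, 10, 16 and Y left out, Rxra-KO had 68 rises and 67 falls in common with Cyp26-E1-KO (15.18 and 13.98 for independent lists) and 54 and 57 with Cyp26-E2-KO (9.91 and 9.83), with correlations of 0.315 and 0.347. RARX-DKO shared 57 rises and 71 falls with Cyp26-E1-KO (25.35 and 27.1 for independent lists) and 52 and 60 with Cyp26-E2-KO (18.12 and 18.98), but also had 31 and 33 genes opposite to Cyp26-E1-KO (24.1 and 28.5) and 18 and 32 opposite to Cyp26-E2-KO (16.9 and 20.4), with correlations of 0.016 and 0.069. Rara-KO shared 16 rises and 13 falls with Cyp26-E1-KO (9.30 and 5.57) and 15 and 8 with Cyp26-E2-KO (6.65 and 3.90), and had 15 and 8 genes opposite to Cyp26-E1-KO (8.86 and 5.85) and 8 and 8 opposite to Cyp26-E2-KO (6.19 and 4.18), with correlations of -0.03 and 0.026. With the same chromosomes left out Rara-KO shared 2 rises and 3 falls with Cyp26-E1-KO (2.00 and 1.47) and 1 and 1 with Cyp26-E2-KO (1.31 and 1.03), and RARX-DKO 21 and 34 (8.45 and 12.9) and 19 and 27 (5.52 and 9.08).

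Rxra-KO and Rxra-OE went in opposite directions in 142 and 139 genes (62.3 and 59.7 for independent lists) and in the same direction in 31 and 23 (62.2 and 59.8), with a correlation of -0.314 across 15976 genes. Cyp26a1, Cyp26b1 and Cyp26c1 fell in the knockout and rose with overexpression, and Foxd3 and Pou3f1 did the reverse. For Rara-KO and Rara-OE the correlation was -0.084, with 27 and 16 genes in opposite directions (9.26 and 5.49) and 6 and 6 in the same (9.49 and 5.36). RARX-DKO and Rxra-OE went in opposite directions in 121 and 138 genes (52.3 and 57.6) and in the same direction in 25 and 25 (52.2 and 57.7), with a correlation of -0.271. Rxra-OE and Cyp26-E1-KO had 882 rises and 698 falls in common (703 and 645.7) and 727 and 735 genes in opposite directions (666.4 and 681.2), with a correlation of 0.042, so the likeness of Rxra-KO to Cyp26-E1-KO was not matched by an opposite relation of Rxra-OE to it. These counts do not tell which changes are direct.

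The tests of Y-chromosome reads and of Rara levels in V-OE were chosen after the Y-linked genes called in Rara-KO and RARX-DKO were seen to have 0 counts, and the test of library depth was set before. Loss of the Y chromosome, library depth or silencing after loss of RARA could give this pattern, and depth is argued against, since 0% of the autosomal genes at or above the lowest WT level of 5.58 CPM (over unscaled library totals) had 0 counts in all 4 libraries. In 4C the lowest share of Y reads in WT or Rxra-KO was 1.47 times (Hoxb-E1) and 2.86 times (Hoxb-E2) the highest share in Rara-KO or RARX-DKO, the direction that loss of the chromosome needs. Loss stays open all the same, since 1527 to 2438 Y fragments were still covered in Rara-KO and RARX-DKO at Hoxb-E1. Rxra-KO, which has Y-linked transcripts, also lay below WT there (0.227% and 0.283% against 0.510% and 0.452%). At the Cyp26 baits Rxra-KO had 0 Y reads, but WT libraries covered only 2 or 3 Y fragments there, so nothing follows from it. Silencing and loss cannot be told apart by V-OE, where Rara stood at 50.21 CPM over unscaled library totals (52.0 CPM with TMM scaling) and the Y-linked genes had 0 to 2 counts. In Rara-OE Ddx3y had 5 and 10 counts and Eif2s3y 12 and 5, and in Rxra-OE these were 0 and 0, and 2 and 2. Low Y-linked counts thus also occurred with Rara expressed, so loss of RARA is not needed for them. The cause in the knockouts is not settled by this.

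The comparison with RARX-DKO replicate 1 below was chosen after the chromosome medians were seen. Genes of chromosome 8 were higher in RARX-DKO replicate 2 than in replicate 1, in 87.4% of 604 genes, with a median difference of 0.374. The pattern was picked by chromosome medians, which a few strongly changed genes hardly move, so this share does not test that explanation. A bias that follows expression level is argued against by the lowest median over expression classes, 0.329. The -0.06 of replicate 1 is part of the pattern itself, so it is no separate test of loss of RARA and RXRA. Both libraries are RARX-DKO by their labels, so that loss alone would not set them apart. Extra copies of chromosome 8 in part of the cells stay open. Medians of the 20-Mb bins were 0.363 to 0.506 in all but the last, at 0.127. Whether chromosome 6, at 0.20 in the same library, has the same origin stays open.

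Both tests of fragment sharing were chosen after the sharing was seen, and no biological explanation was tested. Paired Cyp26 4C libraries shared at least 99.9% of their fragments. Depth that reaches nearly every fragment is argued against, since libraries of different genotypes shared at most 33.5% at the same bait. Whether each pair comes from 1 ligated template stays open, since the 99.9% is the sharing that raised the question and cannot test it. Whether the pairs measure a spread between cultures, and what the contact profiles of other templates of these genotypes would be, stay open too.

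Splits of the enhancer libraries into 3 and 3 are too few, at 10, to give a small share. In each of 6 tests 1 split, the real one, reached the real count. For Cyp26-E1-KO against WT it called 4741 genes, with 2 at most in the others, and 7 lists, with 5 at most. For Cyp26-E2-KO against WT these were 3280 and 1 genes and 9 and 3 lists, and for Cyp26-E2-KO against Cyp26-E1-KO 842 and 0 genes and 8 and 4 lists.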
